A study of Mus musculus with 3 samples.

How the data were processed

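RNA bound by Mettl3 or Zfp217 was measured by RIP-seq in CCE, a line of mouse embryonic stem cells. Per the labels' protocols, nuclei were isolated, the nuclear lysate was incubated with an antibody against Zfp217 or Mettl3, complexes were collected on protein G beads, RNA was extracted with Trizol, and libraries were made with the TruSeq RNA kit. There were 3 libraries: 1 from the Mettl3 immunoprecipitation (RIP), 1 from the Zfp217 RIP, and 1 from the input. Groups were taken from the sample titles and antibody labels. A control immunoprecipitation with an unrelated antibody was not analysed here.

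The authors deposited 2 tables, 1 per antibody, with FPKM values (fragments per kilobase of transcript, scaled to the number of mapped fragments) of the input and the RIP library for each Ensembl transcript, with its symbol, its class and the authors' log2 fold change of RIP over input. Per the submitters' processing notes, CASAVA 1.4, Bowtie2, TopHat2 2.0.8, Cufflinks, Cuffdiff and the mouse build mm9 were used. Their roles, order and settings are not given in the sources used here. The deposited log2 fold change differed from the log2 ratio of the deposited FPKM values by at most 0.00466, with a code for infinity where the input was 0 FPKM. Each table held a selection: the lowest RIP value was 1.00 FPKM in both, and no transcript with an input above 0 was under 1.5-fold higher in the RIP. Transcripts below these limits, or lower in the RIP than in the input, were therefore not listed. The tables had no p-values or significance flags. Both tables used the same input library. Its values in the Mettl3 table were 0.989 times those in the Zfp217 table at the median of 2813 transcripts, and 85.1% of transcripts lay within 0.001 of that factor, so each ratio was taken within its own table.

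The log2 ratio was log2((RIP + 1)/(input + 1)) in FPKM, which understates the ratio of low transcripts. Transcripts with a mean FPKM of RIP and input of at least 1 were kept, and at least 2-fold higher on this scale was the rule of size. With an input at or near 0, a mean of at least 1 already needs a RIP value that passes this rule. Plain FPKM ratios are given for named transcripts, and no fold is given where the input was 0 or under 0.01 FPKM. A fold given beside a gene symbol is that of 1 listed transcript, not of the gene as a whole. No p-value was computed, since each group had 1 library. Comparisons with random lists and resampled intervals describe the spread over genes or transcripts of these libraries, not over replicates. A gene list was described by the median log2 ratio of its members, with 1 transcript per gene (that of the highest mean FPKM), and by the percentile of this median among 10000 random lists of the same size, matched on mean FPKM in 10 bins and drawn from the listed transcripts. Lists with at least 5 members measured were described this way. The 23 gene lists, the rule of size, the rule for named genes and the alternatives, except those named as added, were fixed before the data were examined.

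The design assumed tables of genes with the authors' significance calls and with genes both higher and lower than the input. Being listed stood in for the authors' call, transcripts took the place of genes, and counts of lower genes and of significant genes were left out. The rule for named genes took, for each RIP, the 8 with the highest log2 ratio among those with both FPKM values at least 1, a gene span of at least 300 bases and a symbol for a single gene; Nanog, Sox2, Klf4, Myc, Pou5f1, Mettl3, Mettl14, Wtap and Zfp217 wherever listed; and up to 4 members of each list, 2 with the highest and 2 with the lowest ratios among transcripts with both FPKM values at least 1, which need not be the transcripts behind the list's median. For the overlap it took the 8 with the highest smaller ratio, and for the difference between antibodies the 5 furthest apart each way. The 8 lowest of each table were not named, because the tables end at the authors' lower limit. Some genes that the rule takes are not reported here. Members named for the table that lists them, without a value, were chosen after they were seen.

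GENCODE M21 on GRCm38 gave transcript lengths, GC content, coding and untranslated lengths, the number of transcripts per gene and gene coordinates. No coordinate was taken from the authors' build. Their annotation may hold other transcripts: Sox2 has 1 transcript in M21 and 2 in the tables, so a gene with 1 transcript in M21 may have had its reads split. Transcript identifiers matched for 88.3% of the Mettl3 table and 88.8% of the Zfp217 table. In 21 and 20 transcripts the symbol had been turned into a date, and these symbols matched no list. List sizes counted annotated symbols, older symbols included.

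Depth was estimated from the tables. FPKM values of short noncoding RNAs are whole multiples of the value of 1 read, and the fragment number that made most of them whole was taken: 9600000 for the Mettl3 RIP (19 of 25 short RNAs whole within 0.04 reads, 76.0%) and 6950000 for the Zfp217 RIP (22 of 26, 84.6%), with a mean fragment of 139 bases. For the input, 12 short RNAs gave 5835866 (66.7% whole), the least certain of these numbers. These are numbers after Cuffdiff's scaling, and they rest on few transcripts. At 2000 bases, 1 FPKM then stood for about 17.9 reads in the Mettl3 RIP, 12.9 in the Zfp217 RIP and 10.9 in the input, and at 500 bases for 3.47, 2.51 and 2.11. From these reads an exact (Clopper-Pearson) 95% interval of each RIP to input ratio was made for transcripts of at least 300 bases. For the named transcripts furthest apart, the same kind of interval of the ratio between the antibodies was made from the reads of both RIPs. The intervals cover counting error only, not the assignment of reads to isoforms, PCR copies or differences between preparations.

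For the shared input, 100 sets of 3 libraries with no difference between them were drawn from Poisson counts at the estimated depths. The authors' limits were applied to them for the counts of listed transcripts, but not for the correlations and covariances. On simulated values, the depth fit was off by 1.67% for the 25 short RNAs of the Mettl3 table and by 0.714% for the 26 of the Zfp217 table. All simulated values were exact whole reads, unlike the real ones, so a small error was built in. The fit of the input was not tested this way. Among lists of 20 genes drawn from the 6667 kept Mettl3 transcripts with nothing added, 5.1% fell outside the central 95% of random lists, and 42.0% and 100% lay above it when raised by 0.5 and by 1 on the log2 scale. For the 5248 kept Zfp217 transcripts the shares were 6.0%, 27.5% and 97.7%. In this check the ratios were shuffled over transcripts first, so a share near 5% for unchanged lists follows from the method. Alternatives were another pseudocount, the deposited log2 fold change, other filters on low values, centring on the median, a stricter fold and a minimum gene span. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.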

Results

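Nuclear RNA bound by Mettl3 or by Zfp217 was profiled in CCE mouse embryonic stem cells. Mettl3 is the catalytic subunit of the enzyme that writes m6A, a methyl mark on adenosines of mRNA, and Zfp217 is a zinc finger protein of chromatin complexes. The series asked which RNAs were associated with each protein, and its title ties Zfp217 to m6A. There were 3 libraries, 1 each of Mettl3 RIP, Zfp217 RIP and input, with an estimated depth of 9600000, 6950000 and 5835866 scaled fragments. With no replicates, no p-value was computed, and every ratio compares libraries, not conditions. The Mettl3 table listed 9501 transcripts of 6971 gene symbols, and the Zfp217 table held 8120 transcripts of 5933 symbols. All were above 1 FPKM in the RIP and at least 1.5-fold above the input. The median RIP level was 2.66 FPKM (quartiles 1.54 and 5.88) for Mettl3 and 2.25 FPKM (1.44 and 4.28) for Zfp217. Protein-coding transcripts were 67.4% and 62.6% of the tables, and retained-intron transcripts 11.4% and 14.0%. The input was listed at 0 FPKM for 2983 Mettl3 transcripts (31.4%) and 3157 Zfp217 transcripts (38.9%), and above 0 but under 0.01 FPKM for 415 and 431 more.

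The first comparison asked which transcripts were higher in the Mettl3 RIP than in the input. Among transcripts with both values at least 1 FPKM and a gene span of at least 300 bases, the noncoding RNA Tug1 was highest, at 38.4 FPKM in the RIP and 1.33 in the input, 28.9-fold higher (95% counting interval 21.01 to 42.3). A retained-intron transcript of Psat1, an enzyme of serine synthesis, was 22.9-fold higher (14.2 to 40.9). Mettl3's own mRNA was 4.92-fold higher in the RIP made with the antibody against its protein (16.3 against 3.31 FPKM, interval 3.52 to 7.25). The transcript ENSMUST00000112581 of Nanog, a pluripotency transcription factor, was 2.63-fold higher (38.5 against 14.6 FPKM, interval 2.20 to 3.14). Another Nanog transcript, ENSMUST00000012540, listed for Zfp217 with 18.6 FPKM in the input, was not listed for Mettl3. The ribosomal protein and heat shock mRNAs had high median ratios, but these rested in part on transcripts near 0 FPKM in the input.

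Of the other transcripts with the highest ratios under the same limits, one of Nhp2l1, a U4 snRNP protein, was 22.7-fold higher (29.6 against 1.30 FPKM), with a wide interval of 9.15 to 67.8 because the input held about 4.79 reads. Fermt2, an integrin adaptor, was 14.2-fold higher, and Bag1, a cochaperone of Hsp70, 14.1-fold higher. Tab2, an adaptor of inflammatory kinase signalling, was 13.7-fold higher, Ctdsp2, a phosphatase of RNA polymerase II, 13.2-fold, and the predicted gene Gm13225 12.1-fold (74.6 against 6.18 FPKM). In GRCm38, the Tug1 transcript ENSMUST00000144852 lies in the gene on chromosome 11 from 3639785 to 3649673 (minus strand). The Psat1 transcript ENSMUST00000161707 lies on chromosome 19 from 15904678 to 15947337 (minus strand), Mettl3 on chromosome 14 from 52294841 to 52305128 (minus strand), and Nanog on chromosome 6 from 122707489 to 122714633 (plus strand).

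Among the genes fixed in advance, the main Sox2 transcript was 1.79-fold higher in the Mettl3 RIP (75.8 against 42.2 FPKM, interval 1.62 to 2.00), and a second Sox2 transcript 3.85-fold. The full-length Myc transcript was 1.54-fold higher (interval 1.11 to 2.14). One transcript of Wtap, a regulatory subunit of the m6A enzyme, was 1.68-fold higher (1.19 to 2.38). The Wtap transcripts ENSMUST00000160781 and ENSMUST00000007007, listed for Zfp217 with 5.90 and 5.57 FPKM in the input, were not listed for Mettl3. Klf4 was at 53.6 FPKM in the RIP, but its transcript had only 0.00253 FPKM in the input. Zfp217 mRNA was at 3.63 FPKM against 0.00316 in the input. Both genes have several annotated transcripts, 3 and 5, and no fold is given for them. Pou5f1 was listed with a transcript at 8.54 FPKM against 0, and with another that was 2.03-fold higher with an interval of 0.610 to 8.32. Mettl14 was not listed for Mettl3.

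For Mettl3, 6667 transcripts were kept, with a median log2 ratio of 1.02 (quartiles 0.69 and 1.69). Of these, 3405 transcripts of 2912 symbols were at least 2-fold higher (51.1%). The count was 1969 without transcripts at 0 or under 0.01 FPKM in the input, and 1258 when the input was at least 1 FPKM. Since the table starts at 1.5-fold, both the median and these shares depend on the authors' limit.

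Pluripotency factors had 15 of 24 kept genes at least 2-fold higher in the Mettl3 RIP, with a median log2 ratio of 1.23, at the 86.3 percentile of random lists. A Sall4 transcript of 773 bases was 6.64-fold higher (interval 3.05 to 19.7), a Tet1 transcript of 581 bases 5.42-fold (1.48 to 25.2, from about 2.74 input reads) and Fgf4 1.53-fold. Other transcripts of Sall4 and Tet1, at log2 ratios of 4.30 and 6.68, were at 0 FPKM in the input. For the m6A writers, readers and erasers, 6 of 17 were at least 2-fold higher, with a median of 0.93 (28.8 percentile). Cbll1, another subunit of the m6A enzyme, was 4.35-fold higher, the nuclear reader Ythdc1 1.61-fold and Ythdc2 1.63-fold. Cytosolic ribosomal proteins had a median of 1.68, with 25 of 32 at least 2-fold higher, such as Rps14 (5.29-fold for a transcript of 602 bases). This median lay above the central 95% of random lists, and it was 1.15 (96.8 percentile, inside that range) over the 20 genes left without inputs under 0.01 FPKM. Heat shock proteins and chaperonins had a median of 2.21 over 8 genes (99.6 percentile), of which 4 were left without such inputs. Small noncoding RNAs had a median of 6.80 over 19 genes, and 3 were left. Ribosomal protein reads may be shared with pseudogenes, so their values are uncertain.

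The other lists lay inside the central 95% of random lists in the Mettl3 RIP, with the splicing list at the 5.21 percentile. The members named here are among those with the highest ratios of their list. The lowest were near the 1.5-fold limit, such as Ddx17 (1.51-fold) and Luc7l2 (1.52-fold) of the splicing list and Chd1 (1.51-fold) of the chromatin remodellers. Medians were 1.04 for Polycomb and Trithorax regulators, where Pcgf3 was 3.57-fold and Rybp 3.18-fold higher. They were 1.12 for chromatin remodellers (Arid2 3.68-fold), 0.89 for CoREST, NuRD and CtBP corepressors (Mta1 4.55-fold) and 0.87 for splicing and hnRNP factors (Hnrnpd 5.03-fold, Rbm39 4.48-fold). Immediate early genes had a median of 0.89 (Ier2 2.51-fold, Spry4 2.29-fold) and cell cycle genes 0.94 (Mcm4 5.37-fold, Ccnd2 2.64-fold). Translation factors and tRNA synthetases had a median of 0.97, with a 745-base transcript of Eef1a1, 1 of 8 annotated, 5.94-fold higher. Glycolysis enzymes had a median of 1.02 (the glucose transporter Slc2a3 1.99-fold), oxidative phosphorylation subunits 0.94 (Ndufv3 2.22-fold) and zinc finger proteins 0.92 (Zfp534 6.30-fold, Zfp652 5.67-fold). Nuclear long noncoding RNAs had a median of 0.73 over 6 genes, with Rian at 2.31-fold and Neat1 at 1.77-fold.

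The second comparison asked the same of the Zfp217 RIP. Bag1 mRNA was highest among transcripts with both values at least 1 FPKM and a gene span of at least 300 bases, at 20.98 FPKM against 1.21 in the input, 17.3-fold higher (interval 8.80 to 41.8). The transcript of Nhp2l1 was 15.1-fold higher, and of the zinc transporter Slc39a7 11.3-fold. A transcript of Psip1, a chromatin-bound coactivator, was 12.6-fold higher. The interval of this Psip1 fold was wide, 3.54 to 119, because the input held about 2.23 reads. Scarna2, a small Cajal body RNA, was the most abundant of the named transcripts, at 524 FPKM against 84.4 (6.22-fold, interval 5.20 to 7.52). The main Sox2 mRNA was 2.11-fold higher (90.0 against 42.7 FPKM, interval 1.89 to 2.35). Nanog mRNA was 1.83-fold (1.51 to 2.22) and 1.56-fold higher (1.32 to 1.84) for its transcripts ENSMUST00000112581 and ENSMUST00000012540.

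A retained-intron transcript of Acin1, a splicing-associated protein, was 11.2-fold higher (interval 3.69 to 38.5), Fermt2 10.95-fold and Ebna1bp2, a nucleolar protein, 8.85-fold. Bag1 lies on chromosome 4 from 40936398 to 40948294 (minus strand) and Scarna2 on chromosome 3 from 108554338 to 108554751 (minus strand) in GRCm38. Of the m6A enzyme, Wtap transcripts were 2.19-fold (1.69 to 2.89), 2.07-fold and 1.91-fold higher, Mettl14 was 1.67-fold higher (3.77 against 2.26 FPKM, interval 1.10 to 2.61), and Mettl3 was not listed. Myc was 1.75-fold higher (1.25 to 2.46). Pou5f1 transcripts were 1.86-fold (0.960 to 3.78) and 1.81-fold higher (0.450 to 7.62), both with intervals that include 1. Klf4 was at 51.8 FPKM against 0.00299, and Zfp217's own mRNA at 4.14 FPKM against 0.00373, near 0 in the input as in the other table.

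For Zfp217, 5248 transcripts were kept, with a median log2 ratio of 0.98 (quartiles 0.63 and 1.78), and 2577 transcripts of 2185 symbols were at least 2-fold higher (49.1%). The count was 1062 without inputs at 0 or under 0.01 FPKM, and 519 when the input was at least 1 FPKM. Among transcripts of at least 300 bases, an estimated 28.7% had fewer than 10 reads in this RIP, against 16.5% in the Mettl3 RIP. The ratio interval lay above 1 for 66.5% and 77.6% of them.

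Pluripotency factors had 13 of 22 kept genes at least 2-fold higher in the Zfp217 RIP, with a median log2 ratio of 1.06 (88.8 percentile). Tcl1 was 5.68-fold and Sall4 5.56-fold higher. The m6A genes had 5 of 12 at least 2-fold higher and a median of 0.96 (62.3 percentile), with Rbm15b, a further subunit of the m6A enzyme, at 2.14-fold and Cbll1 at 1.59-fold. Cytosolic ribosomal proteins had a median of 1.29 over 43 genes (99.3 percentile), with Rpl13a 4.57-fold and Rps2 3.28-fold higher, and 0.92 (95.5 percentile, inside the central 95%) over the 28 genes left without inputs under 0.01 FPKM. Small noncoding RNAs had a median of 7.49 over 22 genes, and 1.13 over the 5 left. Heat shock proteins and chaperonins had a median of 1.65 (97.4 percentile, just inside), and 0.84 over the 5 left without such inputs (62.5 percentile), with Hspa5 2.25-fold higher. Mitochondrially encoded genes had a median of 2.89 over 5 genes, and 2 were left.

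Oxidative phosphorylation subunits had a median of 1.15 over 23 genes in the Zfp217 RIP (89.6 percentile), and 0.82 over the 14 left without inputs under 0.01 FPKM, with Atp5j 3.70-fold and Ndufa7 2.75-fold higher. The corepressors had a median of 1.12 (84.9 percentile), with Sin3a at 5.01-fold, Chd4 at 3.55-fold and Hdac1 at 1.65-fold; an Ncor1 transcript at 0 FPKM in the input had a log2 ratio of 2.34, above the 1.98 of Sin3a. Replication-dependent histones had a median of 0.67 over 9 genes. Hist3h2ba was 2.13-fold higher as a plain ratio, and 1 of the 9 genes passed the 2-fold rule. Medians were 0.89 for Polycomb and Trithorax regulators (Kdm6a 3.55-fold, Kdm2b 2.09-fold), 0.76 for remodellers (Arid1a 1.92-fold), 0.89 for splicing and hnRNP factors (Hnrnpd 8.27-fold, Clk1 6.41-fold) and 0.81 for zinc finger proteins (Zfp652 3.56-fold). They were 0.68 for immediate early genes (Jund 2.78-fold, Spry2 2.10-fold), 1.19 for cell cycle genes (Mcm7 2.66-fold, Cdkn1b 2.99-fold), 1.59 for glycolysis enzymes (Slc2a1 1.72-fold; 0.80 over the 6 of 9 genes left without inputs under 0.01 FPKM, 60.8 percentile) and 0.77 for translation factors and tRNA synthetases (Eif4g1 3.64-fold). All of these medians were inside the central 95% of random lists. Most members named here had the highest ratios of their list. The lowest were nearer the 1.5-fold limit, such as Hnrnpu (1.51-fold) and Luc7l2 (1.71-fold) of the splicing list.

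The third comparison asked which transcripts were higher in both RIPs. With both values at least 1 FPKM in each table and a gene span of at least 300 bases, the highest in both were the same transcripts of Nhp2l1 (22.7-fold for Mettl3, 15.1-fold for Zfp217), Bag1 (14.1-fold and 17.3-fold) and Fermt2 (14.2-fold and 10.95-fold). Zbtb44, a zinc finger protein, was 8.90-fold and 8.82-fold higher, and the Acin1 transcript 8.17-fold and 11.2-fold. Txnrd1, a thioredoxin reductase, was 8.58-fold and 7.60-fold higher, the cytochrome oxidase assembly factor Sco2 7.01-fold and 8.13-fold, and Sall4 6.64-fold and 5.56-fold. Both folds of a transcript divide by the same input library, so a low input value raises both at once. For these 8 the input was close to the 1 FPKM limit (1.04 to 1.70 FPKM in the Mettl3 table, about 3.56 to 25.5 reads). Of the pluripotency list, 19 of 40 genes were listed for both antibodies, among them Nanog, Sox2, Klf4, Esrrb, Tbx3 and Dppa4.

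**Figure D1:**
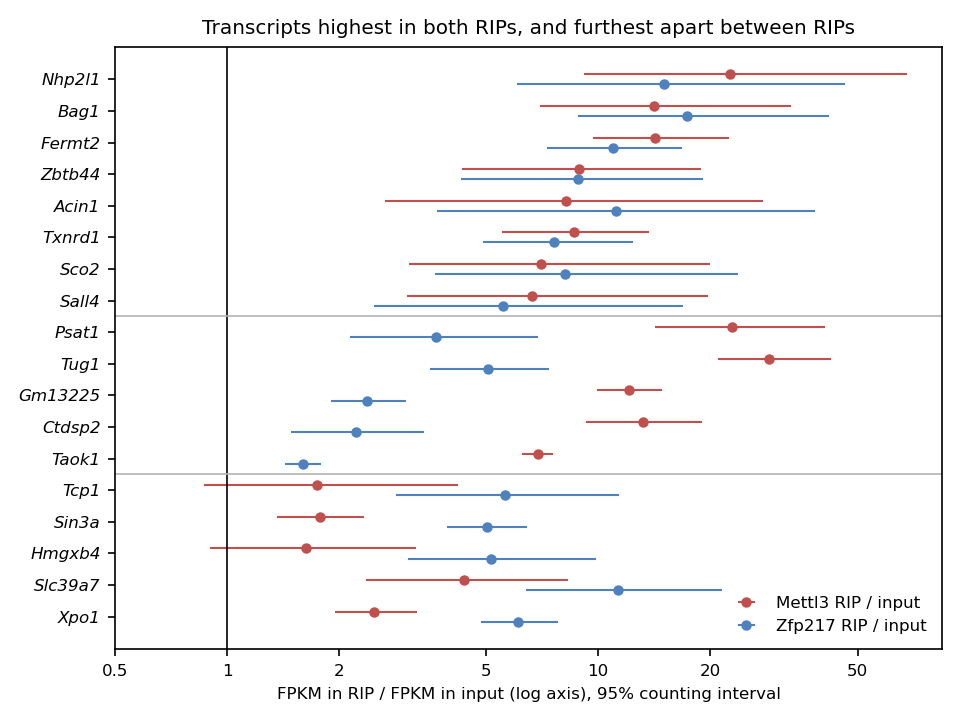
FPKM in the RIP over FPKM in the input (log axis) for the named transcripts, with exact 95% counting intervals from estimated reads; red is Mettl3 and blue is Zfp217. The upper 8 were highest in both RIPs among transcripts with inputs of at least 1 FPKM, the next 5 furthest toward Mettl3 (Tug1, 28.9-fold against 5.06-fold) and the last 5 furthest toward Zfp217 (Sin3a, 1.78-fold against 5.01-fold). Both ratios of a transcript share the input library, so they are not independent.

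Of 13595 transcripts listed in either table, 4026 were in both, 42.4% of the Mettl3 table and 49.6% of the Zfp217 table. With no list of the transcripts that could have been listed, the overlap of independent lists (n1 × n2 / N) would equal 4026 for N of 19163 transcripts, and it would be 544 with all 141767 annotated transcripts. Unchanged libraries that shared the input gave 449 transcripts in both (386 to 507 over 100 simulations), against 3446 observed among the 11625 transcripts of at least 300 bases. Part of the excess over these values may come from the shared input, which could not be split. The simulated transcripts were those listed in the data, and the redrawn libraries were not selected this way, so a lower simulated count was partly built in.

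Of 2663 transcripts kept in both tables, 1024 of 951 symbols were at least 2-fold higher in both. Across transcripts, which are not independent replicates, the log2 ratios correlated with r = 0.85 and rho = 0.67, and the covariance was 1.03. Over the 2261 of at least 300 bases the covariance was 0.462, against 0.0496 in the simulation (0.0401 to 0.0575), a difference of 0.413. The correlation over the same transcripts was 0.75, against 0.59 in the simulation (0.52 to 0.65). In 577 of the 1024 transcripts (56.3%) the input was under 0.01 FPKM, and the filter on the mean alone makes such transcripts pass the rule in both. Without such inputs 447 of 2086 were at least 2-fold higher in both, where independent calls (941 for Mettl3 and 691 for Zfp217) would give 312, and the shared input alone could raise the count above that. With an input of at least 1 FPKM in both tables (1400 transcripts) r was 0.35 and rho 0.25. Over the 1222 of these with at least 300 bases r was 0.33, below the 0.58 in the simulation (0.46 to 0.66). Their covariance was 0.0583, above the 0.0326 in the simulation (0.0260 to 0.0407). These measures point opposite ways, so they do not settle whether the antibodies rank transcripts alike. In the comparisons of r and of covariance with the simulation, the observed values were cut at 1.5-fold and the simulated ones were not. In 134 protein-coding genes with 1 transcript in GENCODE M21, which may not be the authors' annotation, 15 were at least 2-fold higher in both. Independent calls among the 134 would give 12.4. The simulation gave 0.42, counted over the 500 such transcripts listed in either table, a set chosen by the observed lists. The covariance of the 134 was 0.0410, against 0.0423 in the simulation (0.00516 to 0.0898), again with only the observed values cut at 1.5-fold.

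**Figure D2:**
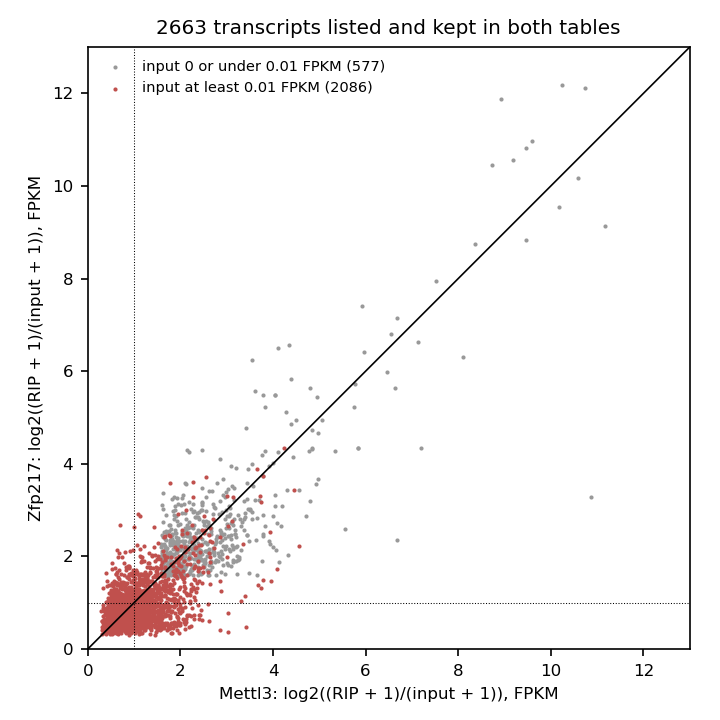
The log2 ratio to input, log2((RIP + 1)/(input + 1)) in FPKM, for Mettl3 (x axis) and Zfp217 (y axis), 1 point per transcript kept in both tables; the solid line marks equal ratios and the dotted lines 2-fold. Grey points are the 577 transcripts with an input under 0.01 FPKM, which make up most of the upper right, and red points the other 2086.

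The listing of gene groups was then compared between the antibodies, by symbol. Of 8547 symbols, 4357 were listed for both, 2614 for Mettl3 alone and 1576 for Zfp217 alone. Zinc finger proteins named Zfp were listed more for Mettl3: 115 for Mettl3 alone, 20 for Zfp217 alone and 125 for both, of 416 annotated. Oxidative phosphorylation subunits were listed more for Zfp217: 20 for Zfp217 alone, such as Atp5d, Cox6a1 and Ndufs3, 7 for Mettl3 alone, such as Cycs and Sdhb, and 16 for both. Replication-dependent histones were at 9 for Zfp217 alone, such as Hist1h2ai and Hist3h2ba, 0 for Mettl3 alone and 1 for both (Hist1h2be). Small noncoding RNAs were at 11 for Mettl3 alone, 14 for Zfp217 alone and 8 for both. Zinc finger proteins, oxidative phosphorylation subunits, histones and small noncoding RNAs lay outside the central 95% of 10000 random lists matched on RIP level, a comparison added after the data were seen, and no other list did. Matched on GC content and length instead, small noncoding RNAs were at the 28.5 percentile, inside that range, and the other 3 lists stayed outside. All 20 listed genes of the CoREST, NuRD and CtBP corepressors, of 26 annotated, were listed for both, where random lists matched on RIP level had a median of 60.0%.

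**Figure D3:**
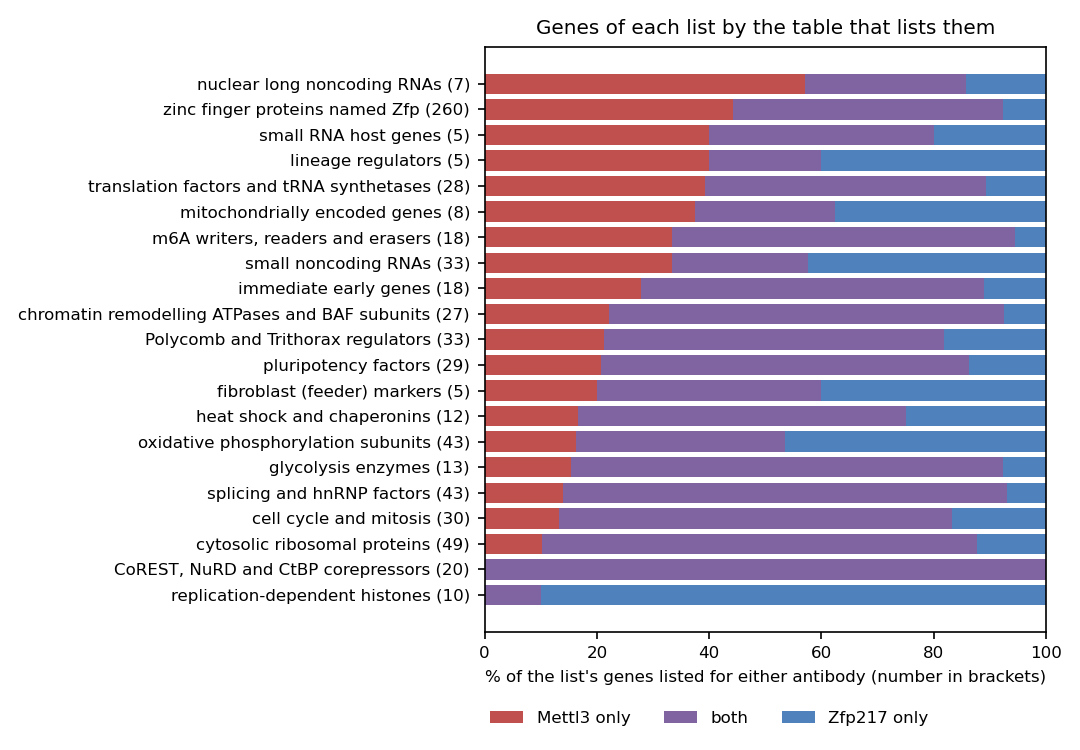
Share of each list's genes (x axis, % of those listed for either antibody, their number in brackets) that were listed for Mettl3 alone (red), both (purple) or Zfp217 alone (blue). The corepressor bar is 100% both, while 9 of 10 histone genes are in the Zfp217 table alone and 115 of 260 zinc finger genes in the Mettl3 table alone.

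Of the m6A genes, 11 of 21 were listed for both, including Wtap, Rbm15, Rbm15b, Ythdf2 and Igf2bp1. As a share of the 18 listed for either (61.1%), this was at the 67.8 percentile of random lists matched on RIP level, inside the central 95%. Another 6 were listed for Mettl3 alone, including Mettl3, Alkbh5, Fto and Ythdf1, and 1 for Zfp217 alone, Mettl14. Pluripotency factors listed for Mettl3 alone were Dppa2, Klf5, Lefty2, Nr5a2, Rif1 and Tet2, and for Zfp217 alone Dppa3, Fbxo15, Klf2 and Stat3. Of all annotated protein-coding symbols, 28.1% were listed for Mettl3, 24.1% for Zfp217 and 18.2% for both. Of markers of other cell types, for Mettl3 and for Zfp217, lineage regulators were at 3 and 3 of 47 (Otx2 for both, 3.09-fold for Mettl3 and 2.68-fold for Zfp217), primitive endoderm markers at 3 and 4 of 20 (Sparc 1.79-fold and 2.10-fold) and fibroblast markers at 3 and 4 of 28. Of the 2-cell-like genes, Eif1a was listed for both (3.21-fold and 1.87-fold) and Zfp352 for Mettl3. Host genes of small RNAs were listed for 5 of 11, with Gas5 at 2.47-fold and 2.88-fold. Neat1 and Meg3 were listed for both antibodies, Malat1 for Zfp217 (1.77-fold for a transcript of 556 bases, with an interval of 0.750 to 4.02 that includes 1) and Tsix for Mettl3. Of 37 mitochondrially encoded genes 8 were listed, 2 of them for both.

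The last comparison set the ratios of both antibodies against each other. Under the limits above, those furthest toward Mettl3 were Psat1 (22.9-fold against 3.65-fold), Tug1 (28.9-fold against 5.06-fold), Gm13225 (12.1-fold against 2.39-fold), Ctdsp2 (13.2-fold against 2.22-fold) and the kinase Taok1 (6.87-fold against 1.60-fold). Those furthest toward Zfp217 were a retained-intron transcript of Tcp1, a chaperonin subunit (5.60-fold against 1.75-fold), the corepressor scaffold Sin3a (5.01-fold against 1.78-fold), Hmgxb4 (5.15-fold against 1.63-fold), Slc39a7 (11.3-fold against 4.35-fold) and the export receptor Xpo1 (6.08-fold against 2.496-fold). Since the input is shared, its counting error does not enter the ratio between the antibodies, and intervals of that ratio were made from the reads of both RIPs alone, after the data were seen. It was 5.72 for Tug1 toward Mettl3 (4.97 to 6.63) and, toward Zfp217, 2.81 for Sin3a (2.39 to 3.31), 3.21 for Tcp1 (2.08 to 5.13) and 2.60 for Slc39a7 (2.01 to 3.40). The interval excluded 1 for each of these 10 transcripts, which were picked as the furthest apart. Of the 2663 transcripts kept in both, 163 were at least 2-fold further up for Mettl3, 72 for Zfp217 and 2428 within 2-fold, and the median difference in log2 ratio was 0.10. Transcripts missing from a table were outside this comparison, so a gene listed for 1 antibody has no measured difference.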

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

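Added after the data were seen were the settings on the input level, on protein-coding transcripts and on estimated reads. No paired analysis was possible because each group had 1 library. Numbers are in the order Mettl3, Zfp217 and both at least 2-fold higher (3405, 2577 and 1024), then Mettl3 and Zfp217 further up by 2-fold (163 and 72), then r (0.85). With no filter on low values they were 5480, 4744 and 1946, with 137 further up for Zfp217 and r = 0.80. With a mean of at least 5 FPKM they were 1014, 434 and 150, then 34 and 20, with r = 0.94. Centred on the median ratios of 1.02 and 0.98 they were 1003, 945 and 365, and at 4-fold 1027, 920 and 361, then 21 and 6. A pseudocount of 0.1 FPKM gave 250 and 109 further up and r = 0.94, the deposited log2 fold change r = 0.97, and gene spans of at least 300 bases r = 0.78. With an input of at least 1 FPKM they were 1258, 519 and 199, with r = 0.35, and without inputs at 0 or under 0.01 FPKM 1969, 1062 and 447. Protein-coding transcripts alone gave 1648 for Zfp217. The stricter filters, the centring and the fold of 4 lower counts by construction, and for the others the cause was not tested. Other counts stayed within 1.5 times. Centring takes the same value off every transcript, so it says nothing of single lists, whose ratios are relative to the listed transcripts. A pseudocount of 0.1 moved 7 list medians, leaving out inputs under 0.01 FPKM 6 of 30, the deposited fold change 3 of 30 and a mean of at least 5 FPKM 1 of 21, and no filter and the gene span none. The planned counts of lower genes and of the authors' significant genes were not run, since the tables hold neither. Estimated RIP reads per transcript were fewer in the Zfp217 table, with a median of 25.6 against 56.0 for Mettl3. Depth, transcript length and FPKM all enter this number. The input, shared by both tables, had the lowest estimated depth.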

Other observations

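Of the tests below, the one on short RNAs, those without genes that have more than 1 transcript in the tables, and the comparisons of lists by the table that lists them, were chosen after the results were seen. Protein-coding transcripts listed for Zfp217 and not for Mettl3 were shorter and richer in GC than the reverse. Their median length was 1891 bases (n = 1914) against 3501 (n = 3067), with 2904 for those listed for both (n = 2421). The 3′ untranslated region had a median of 422 bases against 1565, the coding region 981 against 1345, and the GC content was 52.3% against 47.7%. Retained-intron transcripts were also shorter in the Zfp217 table alone (756 bases, n = 681) than in the Mettl3 table alone (830 bases, n = 618). The Zfp217 RIP had the lower estimated depth of the RIPs (6950000 against 9600000 fragments), and whether depth shaped these differences was not tested. With 1 library each, the antibody cannot be separated from the preparation. Among small noncoding classes, 62 snoRNAs were listed for Mettl3 and 73 for Zfp217, and 51 and 42 miRNA genes.

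Some gene groups were listed for both antibodies more than random lists, and some less. The 20 corepressor genes were all in both tables, among them Kdm1a, Rcor1, Rcor2, Hdac1, Hdac2, Ctbp2, Mbd3 and Sin3a, whose proteins form CoREST, NuRD and related complexes. With random lists matched on the number of annotated transcripts and RIP level the percentile was 99.9. Cytosolic ribosomal proteins were in both for 38 of 49 listed genes (77.6%, 99.0 percentile) and splicing and hnRNP factors for 34 of 43 (79.1%, 97.2 percentile, inside the central 95%), while zinc finger proteins (48.1%, 1.99 percentile) and replication-dependent histones (10% of 10 genes, 2.4 percentile) were below it. Without inputs under 0.01 FPKM, the 20 pluripotency factors left in the Zfp217 RIP had a median log2 ratio of 1.04, at the 98.6 percentile, and the 22 left in the Mettl3 RIP 0.98, at the 60.7 percentile. With 21 lists and several comparisons each, some percentiles this high or low arise by chance.

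Many transcripts were at or near 0 FPKM in the input while clearly present in a RIP, Klf4 among them, and the tests point to the input values of isoforms as a candidate cause. Among protein-coding transcripts for which over 10 input reads would be expected at the RIP level, the input was under 0.01 FPKM for 20 of 591 (3.38%) in genes with 1 transcript in GENCODE M21 and for 2204 of 8150 (27.0%) in the others, a ratio of 0.125 (resampling interval 0.0742 to 0.182), as reads moved between isoforms of a gene would give. The authors' annotation may hold more transcripts (Sox2 has 1 in M21 and 2 in the tables), but without genes that have more than 1 transcript in the tables the ratio was 0.112 (0.0605 to 0.168; 559 transcripts), and transcripts that were not listed could not be checked. For short noncoding RNAs at 0 in the input, 111 of 130 (85.4%, Wilson interval 78.3% to 90.4%) held at most 3 reads in the RIP, so a few reads may set their large ratios. For the longer transcripts at 0, the input would have held a median of 8.03 reads at the RIP level (5036 transcripts). This lay between the bounds of 3 and 10 set in advance, so the rule gave no verdict on too few input reads for the set. For the 44.6% with more than 10 expected reads, 0 reads argues against too few input reads, if the estimated input depth holds. For the 14.9% with under 3, too few reads and a truly low input cannot be told apart. No biological explanation was tested, and real binding of rare isoforms stays open.

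The lean of 4 gene lists to 1 antibody was compared with GC content and length, which differ between the tables. Among random lists matched on both, zinc finger proteins were at the 99.965 percentile toward Mettl3 (228 genes with a value), oxidative phosphorylation subunits at the 0.58 percentile (41 genes) and replication-dependent histones at the 0 percentile (10 genes), so these properties, in 5 classes of each, did not account for the whole lean. The lean of small noncoding RNAs toward Zfp217 was no longer outside random lists (28.5 percentile, against 0.54 when matched on RIP level). Reads shared among zinc finger or histone copies, the low estimated reads of histones (5.81 to 38.9 in the named ones) and differences between the preparations were not tested. A preference of the antibodies' targets may add to it, which 1 library each cannot separate from the preparation.

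For transcripts listed for both antibodies, counting noise of the shared input gave a mean of 449 in simulated unchanged libraries, at most 507, against 3446 observed. Poisson noise redrawn for these transcripts, with none raised in a RIP, thus gave fewer. The simulated transcripts were chosen because they were listed in the data, so a lower simulated count was partly built in. Noise of isoform assignment and of PCR was not drawn, so the test does not exclude noise of the input. Since no transcript was raised, the simulation does not show how much the shared input adds to the overlap of raised transcripts. The covariance of the ratios in genes with 1 transcript in M21 (134) was 0.0868 times that in the others (1665). The values were 0.0410 and 0.472, with a bootstrap interval of the ratio of 0.0174 to 0.165. In the 129 with 1 transcript in the tables it was 0.0728 times (0.0103 to 0.156). Input reads given to other isoforms would give such a gap in protein-coding genes. The input was under 0.01 FPKM in 3 of the 134 and in 334 of the 1665. Real binding of the same isoforms by both proteins was not separated from moved reads. Of 500 protein-coding transcripts of genes with 1 transcript in M21 listed in either table, 170 were listed for both against 13.0 in the simulation (6 to 24), with the same limits. RNA shared by both proteins, or held by beads in any immunoprecipitation, stays open, since a control immunoprecipitation was not analysed here.

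One hypothesis was that transcripts listed for Mettl3 alone carry more m6A consensus sites (DRACH) per kilobase than those listed for Zfp217 alone. The medians were 20.2 and 20.01 sites per kilobase, a difference of 0.235 (bootstrap interval 0.000118 to 0.502). Within 5 classes of GC content the Mettl3 transcripts had the higher median in 0 of 5, with differences from -0.62 to -0.29. By the rule set in advance, a median that was not higher in most classes went against a higher density of sites. The differences within classes have no intervals. The number of sites per transcript was not compared, and m6A itself was not measured here.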
